A study of Mus musculus with 16 samples.

How the data were processed

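Total RNA was taken from the microdissected, flash-frozen cardiac region of single embryos at embryonic day 8.5 and sequenced as paired-end reads of 100 bases at a stated mean of 50 M per sample, with RNA integrity numbers above 9, per the labels' protocols. Reads were aligned with HISAT2 and counted with featureCounts of the Subread package on genome build GRCm38, and DESeq2 was used for normalization and testing, per the submitters' processing notes; versions are not given in the sources used here. The library kit's strand marking is likewise not given in the sources used here, so it is not known whether reads of overlapping genes on opposite strands were told apart.

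The authors deposited 1 table per line with 48526 genes and a column for each of the 8 embryos. Per the file headers and the values, the deposited per-embryo columns hold a normalized signal, that is reads per gene divided by an embryo's DESeq2 size factor within its line, and no raw counts. Each value times its size factor came out as a whole number of reads within a tolerance of 0.01 for 100% of the values of each embryo, so whole reads were recovered from the deposited signal. The same tables hold the authors' p-values and adjusted p-values of DESeq2 for mutant against control, with log2 fold changes as the authors deposited them. No per-sample column was left unused (0 columns). Library totals are sums of the recovered reads. A count of 0 allows up to 3 reads, or 2.53 to 3.84 normalized reads depending on the embryo, and this covers counting error only.

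Groups were taken from the labels: control and mutant embryos of lines G3 and G17, 4 embryos each. The labels give no litter or sequencing batch. The design had named edgeR on counts, and limma on log2(value + 1) if the tables held no counts; since the files held a normalized signal, limma was the main test. In R 4.3.3, limma 3.58.1 was fitted with a mean-variance trend to log2(value + 1), with a pseudocount of 1, for genes with a value of at least 10 in at least 4 embryos, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are differences of group means of log2(value + 1). The pseudocount lowers those of low genes, while embryos near 0 can take them beyond the ratio of the group means. G3 and G17 were each fitted on their own 8 embryos. The common effect and the interaction used all 16 embryos on the deposited values with the line as a term, because the tables were normalized separately. The control embryos of both lines were compared on recovered reads with size factors computed jointly. Targeted-gene values were also compared with an exact two-sided permutation test.

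Gene lists were fixed from textbook knowledge before the data were examined, as were the comparisons, the tests and the rule for named genes: 32 lists with 602 genes, all of which matched the tables. They cover second heart field progenitors, the posterior second heart field, pharyngeal arch mesoderm, sarcomere, cardiac calcium handling, chamber identity, left-right asymmetry, retinoic acid, WNT, BMP, FGF, hedgehog and Notch signalling, ribosome biogenesis, cytosolic ribosomal proteins, mitosis, DNA replication, p53 targets, glycolysis and hypoxia, the respiratory chain, immediate early and heat shock genes, early embryo genes, the GREB1 family, and markers of foregut endoderm, neural tube, neural crest, surface ectoderm, endothelium, primitive erythrocytes, proepicardium, somite and yolk sac. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 32 lists), which compares a list with the other genes; camera with an estimated correlation and fry were alternatives. Of the camera calls, 0 of 15 in G3, 0 of 8 in G17 and 1 of 9 in the common effect held with an estimated correlation. List scores of an embryo are means of log2(value + 1).

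The genes named in the text are, besides Greb1l and Greb1, of 3 kinds. In each line and in the common effect they are the 10 largest rises and the 10 largest falls among called genes with ordinary symbols, a mean of at least 5 CPM in the higher group and no overlap of mutant and control embryos. They are also up to 4 members of each list with the smallest p, and the interaction genes that passed. Coordinates and biotypes are from the GENCODE M21 annotation of GRCm38. Genes named outside this rule, in the closing section, were chosen after their values were seen. Results of some genes under this rule are not reported here, and the counts over named genes leave them out; the counts of called genes and the list statistics hold them.

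The alternatives set before the data were examined were edgeR 4.0.16 (quasi-likelihood, RLE factors), DESeq2 1.42.0 and limma-voom on the recovered reads, the authors' deposited table, no filter or at least 5 CPM, pseudocounts of 0.1 and 5, thresholds of 0.01 and 0.1, size factors without globin and mitochondrial genes, sex as a term, 1 fit of all 16 embryos, and each embryo left out in turn. Alternatives added after the data were seen were edgeR with TMM factors on recovered reads, TMM rescaling of the values, the yolk sac score as a term, and leaving out G17 control 29 and G17 mutant 36.

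Each fit was tested on simulated counts in which 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold. For 4-fold changes limma recovered 69.7% in the G3 design (16998 genes), 69.7% in G17 (16540), 68.2% in the common effect (18579), 40.9% in the interaction (18647) and 59.1% between controls (16632); for 2-fold changes 53.7%, 40.3%, 49.3%, 29.9% and 49.3%. False calls were 7.83%, 8.25%, 7.69%, 6.78% and 9.71% of its calls, against 23.9%, 30.1%, 23.0%, 36.7% and 23.4% for DESeq2.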

Results

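RNA was sequenced from the microdissected cardiac region of 16 mouse embryos at embryonic day 8.5, the stage at which the heart tube forms and begins to loop. Greb1l encodes a nuclear protein related to GREB1, a cofactor of steroid hormone receptors, and the series is titled for its part in the shape of the heart tube. The embryos came from 2 lines on the C57BL/6J background, called G3 and G17, each with its own Greb1l allele. Each line gave 4 embryos labelled mutant and 4 control littermates, so that 4 groups of 4 embryos were compared. Libraries held between 32391421 reads counted in genes (G3 mutant 30) and 49353025 (G3 control 18), and between 18002 and 22689 genes had at least 1 read. The 10 most abundant genes took 4.56% to 5.07% of the reads of a library, and mitochondrial genes 1.49% to 2.13%. By Xist and Y-linked genes, each G3 group held 2 female and 2 male embryos, and all 8 G17 embryos read as female. None of the 120 pairs of libraries differed by as little as sampling noise, and each embryo was counted as a separate replicate.

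The targeted gene was examined first. Greb1l (ENSMUSG00000042942, GRCm38 chromosome 18, 10325177 to 10562940, plus strand, protein coding) fell in the G17 mutants to 42.9% of the control mean, from 9818 ± 508 to 4215 ± 961 normalized reads (SD, n = 4 embryos per group). In line G3 it rose in the libraries labelled mutant to 183% of the control mean, from 10984 ± 1319 to 20144 ± 3377 normalized reads (SD, n = 4). The log2 fold changes were -1.25 ± 0.13 (SE) in G17 (limma, Benjamini-Hochberg adjusted p = 0.000288) and 0.87 ± 0.11 in G3 (adjusted p = 0.000824). Mutant and control embryos did not overlap in either line, and the exact two-sided permutation p of 0.0286 is the smallest that the 70 arrangements of 4 against 4 allow. Because Greb1l RNA was higher in the G3 libraries labelled mutant, RNA abundance did not check those labels for loss of the gene; they are called "labelled mutant" throughout, and every G3 direction rests on the labels. The values cover the whole gene and do not show which exons were read. Greb1 (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886, minus strand), the related gene whose product acts with the oestrogen receptor, passed the test in neither line. Its log2 fold change was 0.11 ± 0.08 in G3 (adjusted p = 0.543) and 0.15 ± 0.11 in G17 (adjusted p = 0.569).

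**Figure D1:**
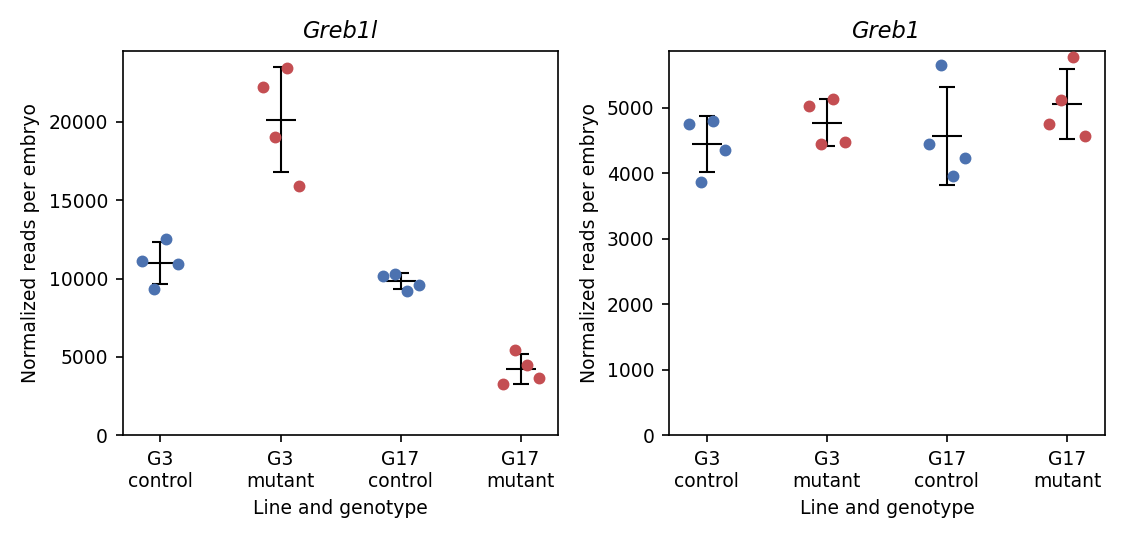
Normalized reads of Greb1l and Greb1 in each of the 16 embryos (points) by group, with the mean and SD of the 4 embryos per group. Greb1l averages 20144 in the libraries labelled G3 mutant and 4215 in the G17 mutants, against 10984 and 9818 in the controls, while the Greb1 means lie between 4442 and 5050.

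The comparison within line G3 asked which genes differ in the cardiac region between the embryos labelled mutant and their control littermates. The transcription factor gene Alx4, active in limb and craniofacial mesenchyme, rose from 316 ± 85.1 to 1402 ± 167 normalized reads (SD, n = 4; log2 fold change 2.18 ± 0.19, SE). Cacna1h, a T-type calcium channel gene of the embryonic heart (chromosome 17, 25374285 to 25433783), rose from 291 ± 66.6 to 1216 ± 118. Pax8 (chromosome 2, 24420560 to 24475599), a transcription factor gene of thyroid, kidney and otic primordia, fell from 623 ± 112 to 65.7 ± 23.5 (log2 fold change -3.29 ± 0.31). Ret, the receptor tyrosine kinase gene of kidney and enteric neuron development, fell from 1250 ± 153 to 380 ± 51.0. In all, 424 genes rose and 293 fell among 18025 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 116 rose and 18 fell more than 2-fold. The 8 embryos separated without overlap at 697 of the 717. Chance alone separates 4 from 4 at 2.86% of genes, and 11.5% of all genes tested separated.

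The genes of this and the like paragraphs below are ranked among called genes of at least 5 CPM whose embryos did not overlap. Of the genes with the largest rises, Wnt7a, a WNT ligand gene, stood at 18.7 ± 28.9 normalized reads in controls and 229 ± 59.6 in the libraries labelled mutant (log2 fold change 5.35 ± 1.14, adjusted p = 0.0191). The SD of its controls exceeds their mean, and the fitted fold of Wnt7a exceeds the ratio of these means. The carboxypeptidase gene Cpa1 (4.66 ± 1.04, adjusted p = 0.0244), Itih2 (4.03 ± 0.47) and the motile cilium regulator gene Foxj1 (2.60 ± 0.47) came next. Mlxipl and Bnc1 (2.31 each), Colgalt2 (2.30 ± 0.36), Nudt13 (2.29 ± 0.37) and Fam81a (2.26 ± 0.48) followed. The steepest falls in this ranking after Pax8 were those of the neurotrophin receptor gene Ngfr (-2.76 ± 0.54), the paired box genes Pax5 (-1.74 ± 0.45, adjusted p = 0.05) and Pax2 (-1.72 ± 0.41), and Ret (-1.72 ± 0.15). They were followed by the growth factor gene Fgf3 (-1.51 ± 0.31), Rtn4rl2 (-1.29 ± 0.30), Emp1 (-1.26 ± 0.24), the necroptosis kinase gene Ripk3 (-1.19 ± 0.29) and the imprinted gene Phlda2 (chromosome 7, 143501545 to 143503150; -1.15 ± 0.12).

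Gene lists for the heart and its precursors were counted in G3. Of 19 second heart field genes, 3 rose and none fell: the signalling ligand gene Bmp4 (0.78 ± 0.16), the Nodal co-receptor gene Tdgf1 (0.94 ± 0.11) and Gata6 (0.41 ± 0.10), a cardiac transcription factor gene on the chromosome of Greb1l (11052064 to 11085635). Adjusted over the list alone, 5 rose and 1 fell, and the list's median (-0.06) and mean (0.09) differ in sign. Of 14 posterior second heart field genes, Wnt2 (0.64 ± 0.15) rose, with a list median of 0.26 (camera adjusted p = 0.00924, and adjusted p = 0.407 with an estimated correlation). Of 7 pharyngeal arch mesoderm genes, 2 rose, Tcf21 (0.81 ± 0.19) among them (median 0.37, adjusted p = 0.101). In the sarcomere list, 1 of 29 genes rose, the slow skeletal troponin gene Tnni1 (0.42 ± 0.10), and 24 of 29 had positive values (median 0.16, adjusted p = 0.00924, and 0.617 with an estimated correlation). In the list for calcium handling and excitation, 3 of 19 rose: Cacna1h, the atrial connexin gene Gja5 (2.05 ± 0.37) and the calcium store gene Hrc (0.63 ± 0.15), with a median of 0.07 (adjusted p = 0.0317, and 0.493 with an estimated correlation). None of 16 genes of chamber identity passed (median -0.01, mean 0.07, adjusted p = 0.424), and 1 of 10 left-right genes rose (median 0.60, adjusted p = 0.059).

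Of 34 genes of ribosome biogenesis measured in G3, 20 fell and none rose (29 fell adjusted over the list alone), with a median of -0.28 (camera adjusted p = 6.94e-27, and adjusted p = 0.0516 with an estimated correlation). The nucleolar helicase gene Ddx21 (chromosome 10, 62580251 to 62602281) fell by 0.64 on the log2 scale (SE 0.04), from 20308 ± 273 to 13024 ± 599 normalized reads, the nucleolin gene Ncl fell by 0.37 (SE 0.03), Gnl3 by 0.42 (SE 0.05) and Nolc1 by 0.37 (SE 0.05). None of 75 cytosolic ribosomal protein genes passed (median -0.02, adjusted p = 0.025, and 0.617 with an estimated correlation). Among 19 p53 targets, Phlda3 (0.91 ± 0.18) and Trp53inp1 (0.69 ± 0.14) rose and none fell, or 4 adjusted over the list alone (median 0.29, adjusted p = 0.00192, and 0.195 with an estimated correlation). None of 25 mitotic genes passed (median 0.03, adjusted p = 0.314), and of 25 genes of DNA replication 1 fell (median -0.03, adjusted p = 0.314). Of 26 genes of glycolysis and hypoxia, the hexokinase gene Hk1 rose, from 2003 ± 456 to 5127 ± 817 (list median 0.10, adjusted p = 0.00924, and 0.617 with an estimated correlation). Of 39 respiratory chain genes, 3 rose, among them Atp5b (0.16 ± 0.03), and cytochrome c gene Cycs fell (-0.41 ± 0.07; list median 0.01, adjusted p = 0.745).

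Signalling lists were counted next in G3. In the retinoic acid list, 1 of 21 genes rose and 1 fell, Crabp2 (-0.38 ± 0.07), and the median (0.08) and mean (-0.01) differ in sign (adjusted p = 0.519). The cyclin gene Ccnd1 (-0.30 ± 0.08) fell among 14 WNT targets (list median -0.06, adjusted p = 0.57). Of 10 BMP response genes 2 rose, the pseudoreceptor gene Bambi (0.50 ± 0.10) among them (median 0.28, adjusted p = 0.0103, and 0.424 with an estimated correlation). The ETS factor gene Etv4 (-0.78 ± 0.18) fell among 10 FGF response genes (median -0.27, adjusted p = 0.00924, and 0.412 with an estimated correlation). None of 8 hedgehog response genes passed (median 0.20, adjusted p = 0.0652), and Notch1 (0.41 ± 0.08) rose among 10 Notch genes (median 0.11, adjusted p = 0.333). The GREB1 family list of 2 genes had a median of 0.49 (adjusted p = 0.019, and 0.407 with an estimated correlation), from Greb1l.

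Markers of other cells that the dissected region could hold were counted in the same way in G3. Of 18 foregut endoderm genes 3 rose (median 0.15, adjusted p = 0.0379), and of 12 surface ectoderm genes 3 rose, including the epithelial adhesion gene Epcam (0.68 ± 0.09; median 0.24, adjusted p = 0.00924). With an estimated correlation these adjusted p values were 0.375 and 0.223. Of 20 neural tube genes 2 rose, among them Sox1 (0.49 ± 0.11), and 1 fell, with a mean of -0.08 and an upward test (adjusted p = 0.519). Of 14 neural crest genes 2 fell, Sox10 (-2.50 ± 0.53) and Foxd3 (-4.90 ± 1.21, from 197 ± 151 to 16.8 ± 26.9 normalized reads), and the list median was -0.14 (adjusted p = 0.0349, and 0.407 with an estimated correlation). Of 14 somite genes Tcf15 fell (-0.71 ± 0.17; median -0.19, adjusted p = 0.0349, and 0.375 with an estimated correlation). Of 24 endothelial genes Plvap fell (-0.39 ± 0.09; median -0.12, adjusted p = 0.258). None of 13 primitive erythrocyte genes passed (median 0.58, adjusted p = 0.151), and 1 of 10 proepicardium genes rose (median 0.18, adjusted p = 0.059).

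Yolk sac visceral endoderm genes, which encode serum proteins and lipid carriers of the embryo, had a median of -0.96 over 18 genes in G3 with no member past the test (camera adjusted p = 0.000408, and adjusted p = 0.491 with an estimated correlation). The median was -0.43 without G3 mutant 23 and -0.58 without G3 control 21. The alpha-fetoprotein gene Afp stood at 3501 ± 2415 in controls and 1288 ± 665 in the libraries labelled mutant (adjusted p = 0.133). Of 10 early embryo and primitive streak genes, the pluripotency genes Pou5f1 (1.61 ± 0.29) and Nanog (chromosome 6, 122707489 to 122714633; 3.34 ± 0.82) rose, Nanog from 13.7 ± 7.78 to 158 ± 112 (list median 0.52, adjusted p = 0.151). Of 10 immediate early and heat shock genes 2 rose, among them Hspb1 (1.81 ± 0.43; list median 0.18, adjusted p = 0.258).

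Without the library G3 mutant 29 the G3 counts were 213 higher and 126 lower, with the yolk sac score as a term 229 and 107, and with DESeq2 679 and 589. The calls of Pax5, Ripk3, Tcf21, Ccnd1 and Hspb1 each ended in 7 of the 8 fits that left out a single embryo, and those of Nanog, Foxd3, Tnni1, Hrc and Etv4 in 6.

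The comparison within line G17 put the same question to the other allele. Pou5f1, the pluripotency factor gene, rose from 256 ± 84.1 to 2706 ± 1146 normalized reads (SD, n = 4; log2 fold change 3.34 ± 0.35). Cacna1h rose from 455 ± 52.4 to 1803 ± 200 and Gja5 from 178 ± 77.2 to 981 ± 124. Pax8 fell from 527 ± 251 to 36.9 ± 43.3. Altogether 331 genes rose and 206 fell among 17706 tested (limma), 154 and 72 of them by more than 2-fold. The 8 embryos separated without overlap at 502 of the 537, against 9.93% of all genes and a chance share of 2.86%.

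The largest rises in the same ranking of G17 were those of Bcl11a, a zinc finger gene of neurons and blood, from 8.72 ± 11.4 to 320 ± 108 (log2 fold change 6.21 ± 1.03), Nanog, from 1.66 ± 1.54 to 213 ± 159 (6.03 ± 1.02), and Prdm12 (5.55 ± 1.15). Large rises were also measured for Cdk5r2 (5.47 ± 1.14), Cpa1 (5.12, adjusted p = 0.0158), Aifm2 (5.09 ± 1.26), Bmerb1 (4.83, adjusted p = 0.0211), Cebpa (4.80 ± 0.92), Fam81a (4.31 ± 1.02) and Bcl11b (3.70 ± 0.49). Nanog lay between 0 and 3.65 normalized reads in the G17 controls, at most 3 reads each, so that its fitted fold depends on the pseudocount. For Bcl11a the SD of the controls exceeds their mean, and its fitted fold exceeds the ratio of its group means. Steep falls in that ranking included those of Pax8 (-4.85 ± 1.10), the organic anion transporter gene Abcc2 (-3.33 ± 0.70), Car7 (-2.75 ± 0.52) and the threonine dehydrogenase gene Tdh (-2.61 ± 0.48). Falls of more than 2 on the log2 scale were also found for Cdhr2 (-2.46 ± 0.49), the immediate early gene Egr1 (-2.39 ± 0.54), Dmrt2 (-2.32 ± 0.53), Tfcp2l1 (-2.30 ± 0.51) and Wnt1 (-2.24 ± 0.48).

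Of 28 sarcomere genes in G17, 3 rose over all genes and 5 adjusted over the list alone, and 25 of 28 had positive values (median 0.31, camera adjusted p = 3.65e-07, and adjusted p = 0.67 with an estimated correlation). The myosin light chain gene Myl3 rose by 0.92 ± 0.18, from 2282 ± 537 to 4286 ± 818 normalized reads, the cardiac troponin gene Tnni3 by 1.19 ± 0.29 and the desmin gene Des by 0.72 ± 0.17. In the list for calcium handling, Cacna1h, Gja5 and Hrc (0.82 ± 0.16) rose among 19 genes (median 0.26, adjusted p = 0.0135, and 0.67 with an estimated correlation). None of 19 second heart field genes passed (median 0.07, adjusted p = 0.627); Tdgf1, at 1.65 ± 0.41, missed the threshold (adjusted p = 0.0502). No gene passed in the lists for the posterior second heart field (median 0.01, mean -0.04), pharyngeal arch mesoderm (0.11), chamber identity (-0.16) or left-right asymmetry (median -0.10 with an upward test), whose adjusted p values were 0.919, 0.41, 0.482 and 0.888.

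Of 34 ribosome biogenesis genes, 7 fell and none rose in G17 (2 to 10 fell in the fits that left out an embryo), or 16 adjusted over the list alone (median -0.22, camera adjusted p = 4.67e-13, and adjusted p = 0.669 with an estimated correlation). Ddx21 fell by 0.48 (SE 0.07), Nolc1 by 0.34 (SE 0.06), and the ribosome assembly genes Bop1 by 0.45 (SE 0.09) and Nop2 by 0.46 (SE 0.09). Among 25 mitotic genes 1 rose (median 0.05, adjusted p = 0.0307) and among 25 genes of DNA replication 2 rose, including the ribonucleotide reductase gene Rrm1 (0.41 ± 0.07; median 0.10, adjusted p = 0.0201); with an estimated correlation these were 0.67 and 0.677. None of 75 cytosolic ribosomal protein genes passed (median -0.02, adjusted p = 0.325). Ddit4, a stress gene, rose from 1875 ± 353 to 4269 ± 1366 among 19 p53 targets (median 0.19, adjusted p = 0.243). Hk1 rose (1.51 ± 0.13) and the glucose transporter gene Slc2a1 fell (-0.60 ± 0.15) in the glycolysis list (median -0.07, adjusted p = 0.309). In all 1 of 39 respiratory chain genes rose (median 0.03, adjusted p = 0.176).

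Among the signalling lists of G17, 1 of the 21 retinoic acid genes rose and 1 fell (median -0.05, adjusted p = 0.243). Sp5 (-0.96 ± 0.19) and Nkd1 (-0.45 ± 0.10) fell among 14 WNT targets (median -0.13, adjusted p = 0.154), and Msx1 (-0.86 ± 0.20) fell and 1 gene rose among the BMP genes (median -0.05, adjusted p = 0.719). Spry1 (-0.83 ± 0.19) fell among the FGF genes (median -0.31, adjusted p = 0.0679), and Boc (0.63 ± 0.14) rose among the hedgehog genes (median -0.08, mean 0.05, adjusted p = 0.627). Notch1 (0.79 ± 0.12) rose and the glycosyltransferase gene Lfng (-0.93 ± 0.19) fell among the Notch genes (median 0.10, adjusted p = 0.435), and the GREB1 family median was -0.55 (adjusted p = 0.154).

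Of 18 yolk sac genes 9 fell in the G17 mutants, or 16 lower and 1 higher adjusted over the list alone, with a median of -2.24 (camera adjusted p = 3.4e-12, and adjusted p = 0.67 with an estimated correlation). The apolipoprotein genes Apob (-2.55 ± 0.54) and Apom (-2.27 ± 0.49), the endocytic receptor gene Cubn (-2.64 ± 0.57) and the transthyretin gene Ttr (-2.12 ± 0.46) fell. Apob stood at 43804 ± 34209 normalized reads in the controls, whose spread approached their mean, and the yolk sac genes called ranged from 0 to 14 over the fits that left out an embryo. They were 0 without G17 control 35 or 37 or G17 mutant 36, 41 or 42, and 0 without G17 control 29 and G17 mutant 36 together. Tdh, Car7, Abcc2 and Cdhr2 fell beside this list. The foregut endoderm list, with 1 gene higher and 1 lower (1 and 6 adjusted over the list alone), had a median of -0.12 (adjusted p = 0.157). Of 20 neural tube genes 3 rose, including Sox1 (0.81 ± 0.15) and the radial glia gene Fabp7 (2.08 ± 0.33; median 0.35, adjusted p = 0.0253, and 0.67 with an estimated correlation). Of 10 early embryo genes 2 rose, Pou5f1 and Nanog, and 1 fell (median 1.37, adjusted p = 0.0261, and 0.67 with an estimated correlation).

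Tcf15 (-1.13 ± 0.24) and Lfng were the 2 of 14 somite genes that fell in G17 (median -0.36, adjusted p = 0.0679), and none of 13 neural crest genes passed (median -0.13, adjusted p = 0.0908). Foxd3 was not among the 13, because it did not meet the filter on low values in G17. Epcam (0.56 ± 0.10) rose among 12 surface ectoderm genes (median -0.18, adjusted p = 0.719). No endothelial (median -0.13), erythrocyte (0.17) or proepicardium gene (median -0.13, mean 0.32) passed, and Hspb1 (2.05 ± 0.19) rose and Egr1 fell among the immediate early and heat shock genes (median -0.10). Their adjusted p values were 0.391, 0.624, 0.856 and 0.624. With the yolk sac score as a term the G17 counts were 120 higher and 27 lower, without the library G17 mutant 42 they were 169 and 50, and DESeq2 gave 565 and 507. Of the 53 named-gene results in G17, 40 lost their call with the yolk sac term. Without G17 control 29 and G17 mutant 36, 19 of 52 lost it. In the fits that left out a single embryo, 137 of 420 values lost it. Without the libraries G17 control 29, which had the highest yolk sac score, and G17 mutant 36, which held a trace of Y-linked reads, 273 genes were higher and 90 lower, and 6 of the 8 lists no longer passed: sarcomere, calcium handling, mitotic, DNA replication, neural tube and early embryo genes (adjusted p = 0.0956, 0.112, 0.214, 0.139, 0.266 and 0.552). The FGF response, neural crest and somite lists passed there instead.

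**Figure D2:**
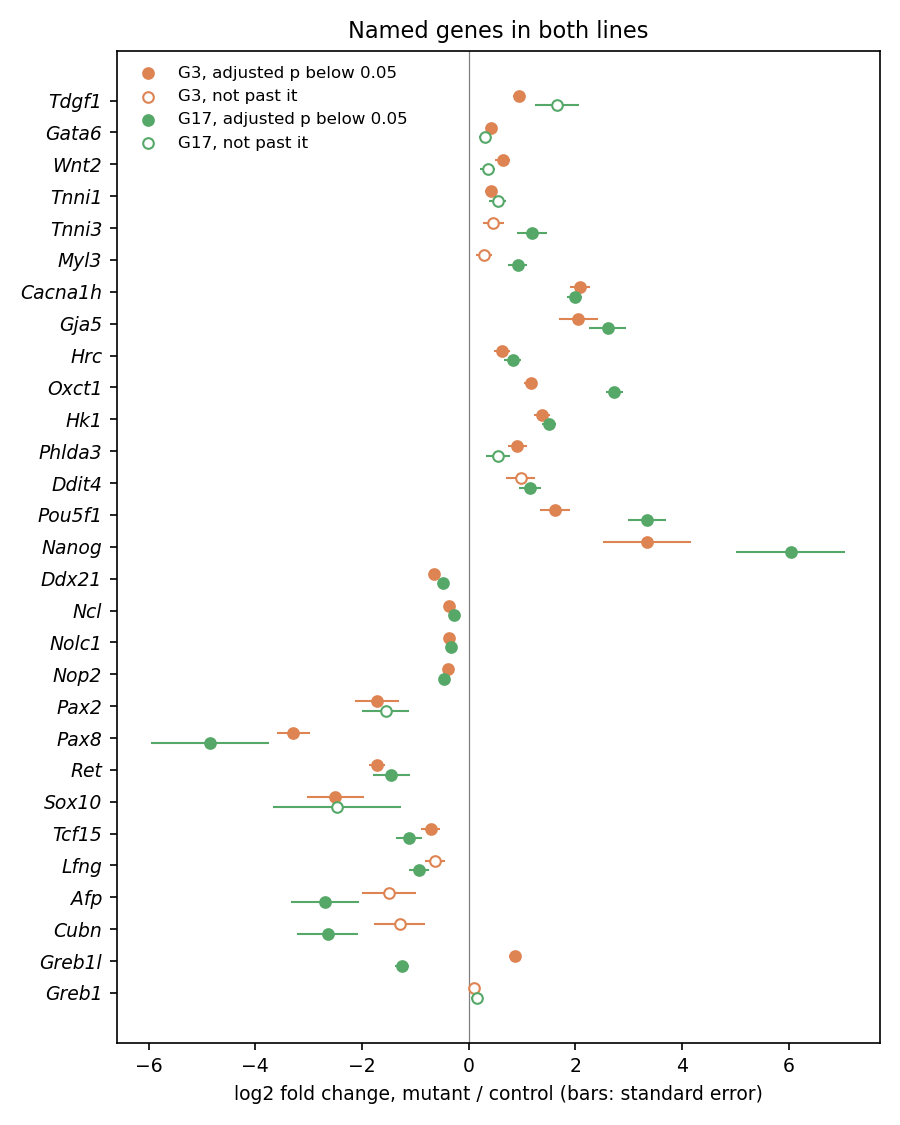
Log2 fold change (mutant over control, ± SE) of 29 named genes in lines G3 and G17, 4 embryos per group, with filled points for an adjusted p below 0.05. Greb1l is the gene called in opposite directions, at 0.87 in G3 and -1.25 in G17, whereas Cacna1h lies at 2.09 and 1.98 and Pax8 at -3.29 and -4.85.

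The mean effect over both lines was tested with the line as a term. A gene can pass in it through a single line, so a call does not by itself show a change in both. Cacna1h rose by 2.03 ± 0.11 (adjusted p = 2.88e-10), Gja5 by 2.33 ± 0.27, Hk1 by 1.44 ± 0.11 and Pou5f1 by 2.48 ± 0.31 (log2, SE, 16 embryos). Pax8 fell by 4.07 (SE 0.64), Phlda2 by 1.55 (SE 0.19) and Ddx21 by 0.56 (SE 0.05; adjusted p = 6.02e-08). In total 1002 genes rose and 878 fell among 20010 (limma), 296 and 128 by more than 2-fold. At 573 of the 1880 the embryos separated without overlap within both lines, as did 2.94% of all genes tested, where chance separates 0.0816% in both lines at once. Greb1l itself, moving in opposite directions, had a mean effect of -0.19 ± 0.25 (adjusted p = 0.723), and Greb1 one of 0.13 ± 0.07 (adjusted p = 0.308).

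In the same ranking, the largest rises over both lines were those of Bmerb1 (5.45 ± 0.72), Cpa1 (4.89 ± 0.80), Nanog (4.68 ± 0.71), Aifm2 (4.66 ± 0.87), Cebpa (4.17 ± 0.75) and Cdk5r2 (3.83 ± 0.74). Itih2 (3.81 ± 0.37), Prdm12 (3.79 ± 0.75), Fam81a (3.28 ± 0.64) and the GABA transporter gene Slc6a13 (3.11 ± 0.36) followed. After Pax8 the falls included the pyruvate kinase gene Pklr (-2.34 ± 0.70), Cdhr2 (-2.02 ± 0.39), Dmrt2 (-1.85 ± 0.35), Wnt1 (-1.64 ± 0.33), the membrane protein gene Emp1 (to 0.353 of the control level), Gpr155 (-1.15 ± 0.29), Plcb1 (-1.05 ± 0.24) and Fndc5 (-1.03 ± 0.21). The call of Pklr ended in 7 of the 16 fits that left out an embryo.

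In the ribosome biogenesis list 27 of 34 genes fell and none rose in the common effect, or 29 adjusted over the list alone (median -0.26, camera adjusted p = 4.03e-26). It was the list whose call held with an estimated correlation (adjusted p = 0.0149); the other camera calls were lost. Ncl fell by 0.33 (SE 0.04), Nop2 by 0.43 (SE 0.05) and Nolc1 by 0.35 (SE 0.04), while 4 of 75 cytosolic ribosomal protein genes, Rpl35 (-0.14 ± 0.04) among them, fell over all genes and none adjusted over the list alone (median -0.02, adjusted p = 0.058). Among 20 p53 targets 5 rose, including Ddit4 (1.06 ± 0.19), Phlda3 (0.73 ± 0.15) and Trp53inp1 (0.65 ± 0.12), and adjusted over the list alone 9 rose and 2 fell (median 0.25, adjusted p = 0.00517, and 0.308 with an estimated correlation). Sarcomere genes rose at 5 of 29, with Tnni1 (0.48 ± 0.10), Tnni3 (0.82 ± 0.20), Myl3 (0.60 ± 0.15) and the Z-disc gene Ldb3 (0.57 ± 0.12), and none fell (median 0.23, adjusted p = 7.09e-06, and 0.7 with an estimated correlation). In the calcium handling list 5 of 19 rose, including Hrc (0.73 ± 0.11; median 0.11, adjusted p = 0.0101, and 0.7 with an estimated correlation).

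Among progenitor genes, Tdgf1 (1.29 ± 0.25), Gata6 (0.36 ± 0.08), Wnt2 (0.49 ± 0.11), Bmp4 (0.48 ± 0.15) and Tbx5 (0.24 ± 0.07) rose in the common effect, the calls of Bmp4 and Tbx5 ending in 12 and 10 of the 16 fits without an embryo. Their lists did not pass. The second heart field list had 3 of 19 genes higher (median 0.05, adjusted p = 0.445). The posterior second heart field list had 2 of 14 (median 0.10, adjusted p = 0.247), and the pharyngeal arch list had 1 of 7, Tcf21 (0.90 ± 0.25; median 0.42, adjusted p = 0.247). Of 21 retinoic acid genes 2 rose, Tbx5 among them, and 3 fell (median -0.07, adjusted p = 0.802, with an upward fry test). Of 10 proepicardium genes 2 rose, Tcf21 and the retinal dehydrogenase gene Aldh1a1 (3.91 ± 0.83), and 1 fell (median 0.08, adjusted p = 0.317). Of 10 FGF response genes 3 fell, Spry1 (-0.64 ± 0.14) among them (median -0.28, adjusted p = 0.0149, and 0.7 with an estimated correlation). Lfng fell (-0.78 ± 0.13) and Notch1 rose (0.60 ± 0.08) in the Notch list (median 0.07, adjusted p = 0.341).

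Of 14 neural crest genes 4 fell in the common effect, including Sox10 (-2.48 ± 0.68), Tfap2b (-2.84 ± 0.79) and Foxd3, which stood at 0 in all 4 G17 mutants and at 183 ± 188 normalized reads in the G17 controls (list median -0.25, adjusted p = 0.0259, and 0.553 with an estimated correlation). Tcf15 (-0.92 ± 0.16) and Lfng were the 2 of 14 somite genes that fell (median -0.22, adjusted p = 0.0283, and 0.553 with an estimated correlation), and Pax2 fell by 1.64 (SE 0.32) in the neural tube list, in which 4 of 23 genes rose (median 0.18, adjusted p = 0.258). Of 19 yolk sac genes 12 fell (6 without G17 control 29 and G17 mutant 36), with Afp (-2.10 ± 0.48), Cubn (-1.97 ± 0.44) and Apob (-1.84 ± 0.42; median -1.62, adjusted p = 2.52e-09, and 0.553 with an estimated correlation). Of 11 early embryo genes 3 rose, Pou5f1, Nanog and Mixl1 (3.28 ± 0.79), and 1 fell (median 1.02, adjusted p = 0.0386, and 0.553 with an estimated correlation). The remaining lists did not pass, and of these the surface ectoderm (median 0.18, mean -0.07) and foregut endoderm lists (median -0.06 with an upward fry test) gave mixed signs. With the yolk sac score as a term the common effect held 576 genes higher and 367 lower.

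**Figure D3:**
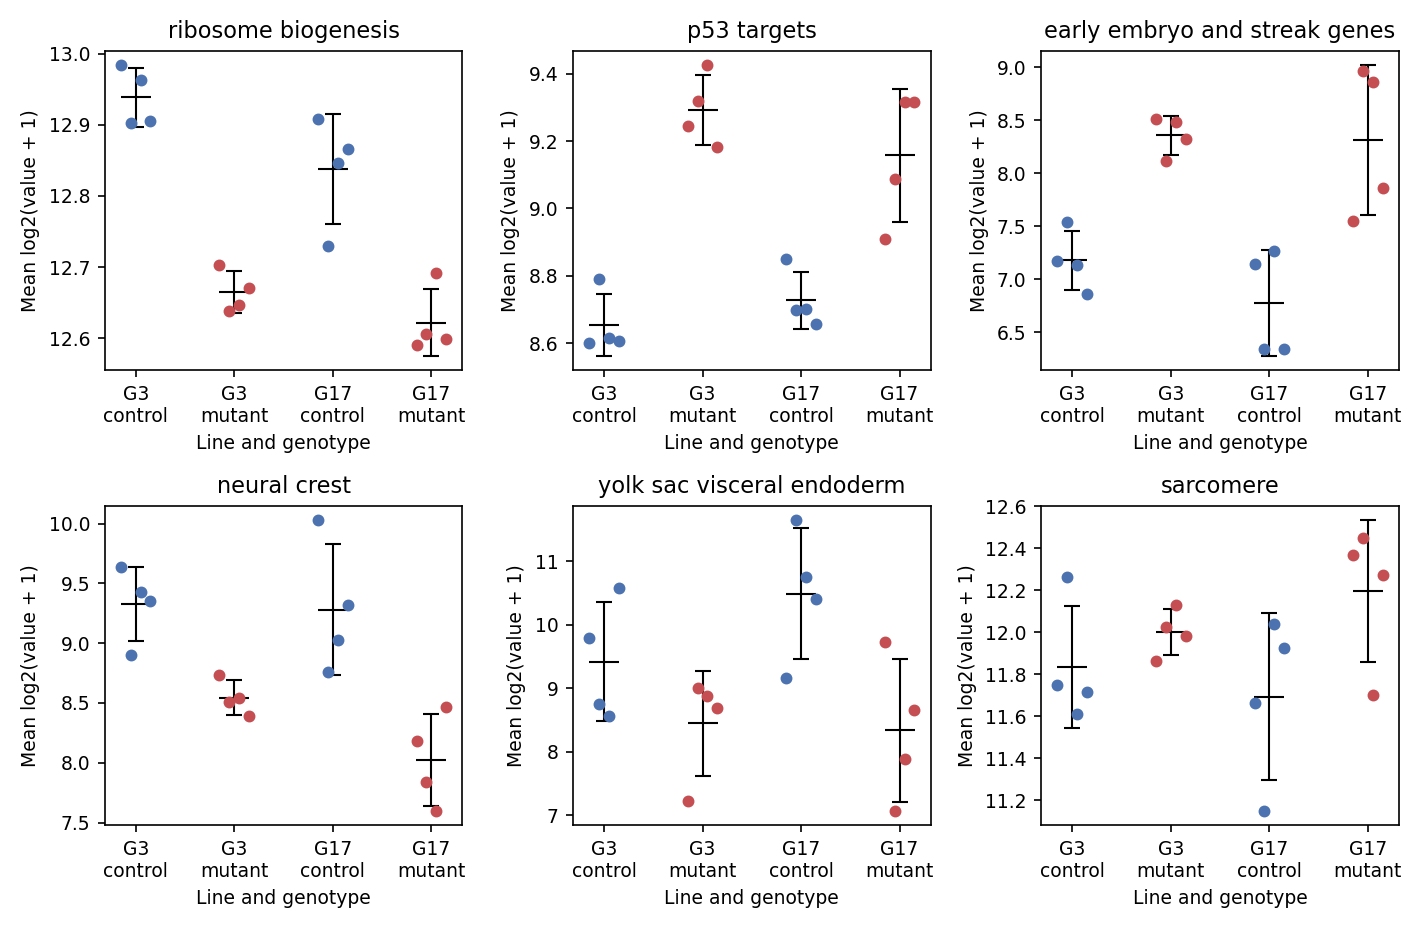
Mean log2(value + 1) of 6 gene lists in each of the 16 embryos (points) by group, with the mean and SD of the 4 embryos per group. The ribosome biogenesis score was lower in the embryos labelled mutant by 0.27 in G3 and by 0.22 in G17, and the yolk sac score varied widely among control embryos.

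The difference between the lines' effects was tested as an interaction, and 2 of 20010 genes passed (limma), with 1276 at an unadjusted p under 0.05. Greb1l differed by 2.11 ± 0.19 (log2, G3 minus G17; adjusted p = 9.24e-06). Oxct1 (ENSMUSG00000022186, chromosome 15, 4026383 to 4155344), the enzyme gene that opens the use of ketone bodies, differed by -1.57 ± 0.20 (adjusted p = 0.00196). It rose by 1.16 ± 0.12 in G3, from 737 ± 67.2 to 1649 ± 182 normalized reads, and by 2.73 ± 0.16 in G17, from 683 ± 158 to 4446 ± 355. By camera 13 of 32 lists differed, sarcomere genes being lower (median difference -0.18) and foregut endoderm genes higher (0.43) in G3 relative to G17, and none of the 13 held with an estimated correlation. DESeq2 on the recovered reads called 8 genes higher and 7 lower.

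Control embryos of the lines were compared to measure how far lines and litters differ without the mutation. No gene of 17816 passed with limma, against 1259 at an unadjusted p under 0.05. EdgeR and limma-voom also called 0, DESeq2 called 12 higher and 21 lower in G17, and limma with sex as a term called 1. Yolk sac genes had a median of 1.14 in G17 controls relative to G3 controls, with 18 of 19 higher (camera adjusted p = 7.87e-10, and adjusted p = 0.457 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.11 and were lower at 70 of 75 (adjusted p = 1.54e-21, and 0.292 with an estimated correlation). Primitive erythrocyte genes had a median of 1.46 and were higher at 11 of 14 (adjusted p = 0.00276, and 0.457 with an estimated correlation). Ribosome biogenesis genes had a median of -0.12 and were lower at 32 of 34 (adjusted p = 7.87e-10, and 0.457 with an estimated correlation). In all 11 of 32 lists passed camera between the controls, and none of them did with an estimated correlation. Line, litter and any batch cannot be told apart in this comparison. Sex was unbalanced in it as well, since the G17 controls all read as female and the G3 controls held both sexes.

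The overlap of the lines was measured over the 17108 genes tested in both, which share no control libraries. The lines shared 191 genes called higher, against 8.09 for independent lists of 423 and 327, and 47 called lower, against 3.49 for lists of 291 and 205 (Fisher's exact p = 3.2e-235 and 8.82e-40, genes not being independent). Of the 239 genes called in both lines, 1 went in opposite directions, Greb1l. Of the genes called in G3, 94.96% had the same sign in G17, and of those called in G17, 97.2% had it in G3, against 64.3% of all genes. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.296 (Spearman's rho 0.327), and over the 11381 genes of at least 5 CPM it was 0.646. With the yolk sac score as a term 77 genes were shared higher and 11 lower, and without G17 control 35 the lines shared 19 called lower.

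**Figure D4:**
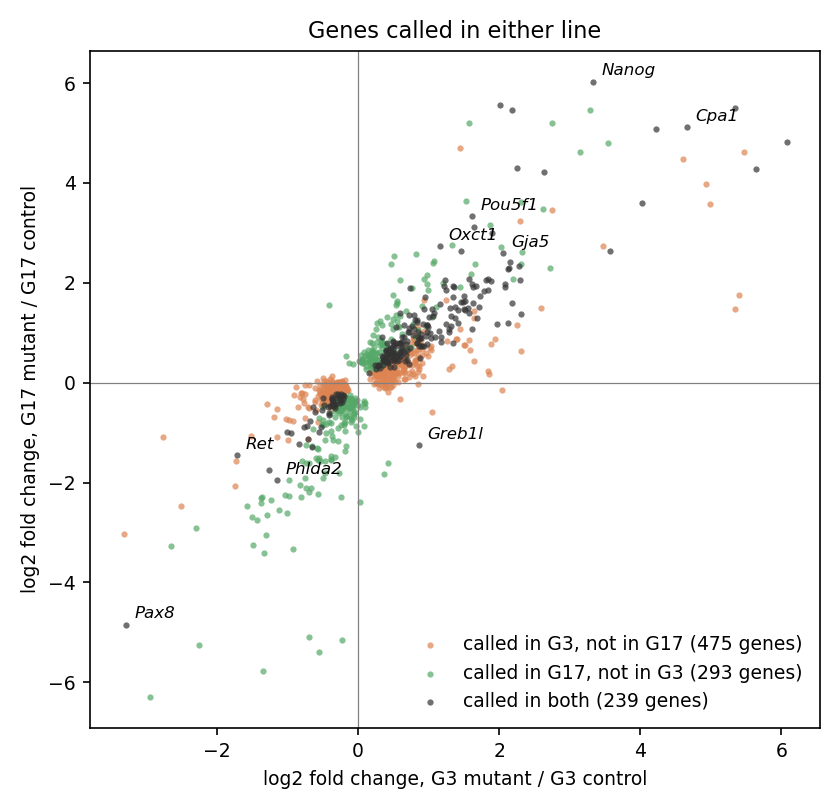
Log2 fold change in line G3 (horizontal axis) against line G17 (vertical axis) for each gene called in either line, coloured by the line or lines that called it. The 239 genes called in both lines lie in the lower left or upper right except Greb1l, which lies at 0.87 and -1.25. The correlation over the 1007 genes called in either is 0.832, and these genes were selected on the same fold changes. Over all 17108 genes tested in both lines it is 0.296.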

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

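The tests of swapped labels, of reads shared with Greb1, of a later stage and of yolk sac carry-over were chosen after the results were seen, as were the yolk sac term and the fit without the doubted libraries; the other tests in this part were set beforehand. What stood out were embryos far from the rest of their group, effects that differed between the lines, and reads from genes outside the comparisons.

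Greb1l RNA moved in opposite directions, and the lines differed by 2.11 (log2, G3 minus G17). A swap of genotype labels in either line is argued against by the other genes: 97.4% of the 531 other genes called in G17 had the same sign in G3, and a swap would have turned most of them around. Reads of the paralog Greb1 counted as Greb1l are argued against by its mean, which changed by 330 normalized reads (SE 281) in the G3 libraries labelled mutant while Greb1l gained 9160, and by the 0 shared sequences among the 11108 of 50 bases in Greb1l. What remains open, as a hypothesis, is that the alleles differ, so that the RNA of the G3 allele may be made or kept at a higher level; no value here shows which exons it holds.

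Of 34 ribosome biogenesis genes, 20 were called lower in G3, 7 in G17 and 27 in the common effect, where the list held with an estimated correlation (adjusted p = 0.0149), but not in G3 (0.0516), in G17 (0.669) or between controls (median -0.12, adjusted p = 0.457). A depth or normalization shift common to genes of like expression is argued against by the list median of -0.26. It lay below all of 10000 lists matched on expression (percentile 0.009999), 95% of which had medians between -0.08 and 0.02. These lists were drawn gene by gene and do not carry the correlation among members. The ribosome biogenesis list also differed between the control groups (median -0.12), so a technical shift of this list alone is not excluded. Yolk sac content is argued against by the fit with the yolk sac score as a term, in which the median was -0.30 and 25 of 27 called members stayed called. A different stage of the mutants cannot be told apart: the early embryo score was higher by 1.36 (exact permutation p = 0.000408), but 3 of 11 members were called higher and 1 lower, and the list missed the threshold with an estimated correlation (camera adjusted p = 0.553). An effect of the genotype stays open beside it, and growth delay was not tested separately.

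Of the yolk sac genes, 0 of 18 were called lower in G3, 9 of 18 in G17 and 12 of 19 in the common effect, and the median effect differed by 1.29 between the lines (G3 minus G17); with an estimated correlation none of these list calls held (adjusted p = 0.491, 0.67, 0.553 and 0.565). The yolk sac list also had a higher median in G17 controls than in G3 controls. The difference between the lines' effects therefore cannot be told apart from a difference between their controls. The library G17 control 29 alone is argued against, since the G17 median was -1.82 without it and -2.24 with it. Carry-over of yolk sac tissue in some dissections could account for the pattern: members deviated together within groups, with a mean pairwise correlation of 0.661 across embryos against -0.04 to 0.06 for 1000 matched lists. Other lists moved together as well, with an estimated correlation in G3 of 0.63 for sarcomere and 0.56 for glycolysis and hypoxia. The correlation therefore does not tell carry-over from co-expression. The retinoic acid list also holds 1 of its genes, Cyp26a1, and how many the cardiac region expresses itself was not measured; Afp and Apob were abundant in it. A lower yolk sac expression in the mutants themselves was not tested apart from this and stays open.

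In line G3, single values lay apart from the rest of their group. G3 control 16 had the lowest Nanog (2.12 normalized reads, next 15.96) and the highest Mixl1 (20.2, the others 0). G3 control 18 had the lowest Prdm12 (16.9, next 67.6) and the highest p53 target score (8.79, next 8.62). G3 control 21 had the highest Gpr155 (291, next 135) and the lowest FGF response score (10.62). Among the libraries labelled G3 mutant, number 23 had the lowest Itih2 (152, next 316), Afp (307, next 1457), Cdhr2 (35.2, next 104) and Fabp3 (393, next 603) and the highest Acat2 (3854, next 3187). Number 31 had the lowest Fgf3 (101, next 202) and Ddit4 (2067, next 5175) and the highest Gata6 (7189, next 5661), and number 29 the lowest Notch response score (9.03).

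In line G17, control 20 had the highest Bop1 (5965, next 5044), Notch1 (3033, next 2489), Sox1 (3114, next 2136) and Tfap2b (228, next 57.2), the lowest Itih2 (8.49, next 38.9) and Emp1 (231, next 407) and the lowest mitochondrial share (1.75%, next 2.07%). Control 29 had the lowest Pax8 (156, next 608) and Tdgf1 (195, next 836), the highest Slc2a1 (83731, next 50594) and the lowest second heart field score (10.02, next 10.63). Control 37 had no reads of Fam81a (0, next 30.4) and the highest Snrpd1 (7955, next 6717), and control 35 the highest chamber identity score (9.96, next 9.57). Among the G17 mutants, number 41 had the lowest Myl3 (3084, next 4557), Hk1 (4852, next 6799), Tcf21 (219, next 508) and Sox10 (0, next 29.6), the highest ribosome biogenesis score (12.69, next 12.61) and the lowest BMP response (10.38, next 10.85) and primitive erythrocyte scores (3.76, next 6.15). Mutant 33 had the lowest Slc6a13 (187, next 225) and the highest Phlda2 (1201, next 665), mutant 36 the lowest Fndc5 (82.6, next 212) and mutant 42 the lowest Aldh1a1 (22.1, next 96.5). Such gaps were found in 40 of 540 groups (7.41%), where chance flags about 1 in 20 groups, and G17 control 20 and G17 mutant 41 held 7 each.

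Besides Greb1l, Oxct1 differed between the lines by -1.57 (log2, G3 minus G17), and 13 lists differed by camera, none of them with an estimated correlation. Median differences were 0.23 for the posterior second heart field, -0.18 for sarcomere, 0.14 for retinoic acid signalling, -0.058 for ribosome biogenesis, -0.11 for DNA replication, 0.14 for glycolysis and hypoxia, 0.34 for BMP response, 0.43 for both foregut endoderm and surface ectoderm, -0.32 for neural tube, 1.29 for yolk sac, 0.37 for immediate early and heat shock genes and 1.03 for the GREB1 family. Outside the main measurement, G17 mutant 36, which reads as female, held 62.2 normalized reads of Y-linked genes in sum, against 0 in the other female embryos. G3 control 18, which reads as male, held 398 normalized reads of Xist. The other male embryos held 53.5 (G3 control 21), 108 (G3 mutant 23) and 8.97 (G3 mutant 30). G3 control 18 was left out only in the fits that dropped single embryos, where G3 gave 556 genes higher and 329 lower.

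The genes called in G3 (717) exceeded every other split of the 8 embryos, of which the highest, the split by sex, called 7, so that 1 of 35 splits gave as many. In G17 (537) 1 of 35 gave as many, the highest other calling 45, and in the common effect (1880) 1 of 100, the highest other calling 2. In each case the 1 is the split by genotype itself, so 1 of 35 is the smallest share a line allows. The other splits mix genotypes within their groups, which raises the spread there and lowers their calls. They therefore do not exclude chance. Genes called in both lines in one direction (238) were matched by 1 of 100 pairs of splits, the highest other giving 0. The interaction called 2, Greb1l and Oxct1, and 7 of 100 splits of the 16 embryos gave as many, with up to 106. Genotypes were redrawn separately in each line, so unlike shares of mutants turn the common effect into a difference between lines. These splits therefore do not decide about chance for this count. Between the control groups, where 0 genes were called, the splits decide nothing about chance, since 35 of 35 reach that count; one other split gave 74. A control split that calls this many genes points to a structure of the samples, and what its embryos share was not tested. For the number of lists past camera chance is not excluded: 2 of 35 splits gave at least the 15 of G3 (highest other 17), 15 of 35 the 8 of G17 (15), and 22 of 100 the 9 of the common effect (17).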

How the results depend on the processing

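The edgeR fit with TMM factors, the TMM rescaling, the yolk sac term and the fit without the doubted libraries (G17 control 29 and G17 mutant 36) were chosen after the data were seen. Of 5006 values of the 187 named-gene results, 4303 stayed on their side of the threshold, 695 lost it, 8 gained it and 0 reversed. A reversal was counted, for genes and lists alike, only where the main fit or the alternative passed the threshold. Sign changes of results that passed in neither were counted as staying. Alternatives that changed only the threshold reused the main fold changes and could not reverse. Of 1568 list values, 1343 stayed, 134 lost the call, 87 gained it and 4 reversed. These 4 were in G17 with the yolk sac term: second heart field -0.46, neural tube -0.19, endothelium 0.19, and DNA replication, whose test turned although its median was 0.0202. No paired analysis was possible because the labels give no litter by which mutants and controls could be paired. Sex as a term was not run within G17, where all embryos read as female.

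Counts of genes higher and lower moved more than 1.5 times as follows; the cause was not tested except for the thresholds, which set it. With DESeq2 they were 679 and 589 in G3, 565 and 507 in G17, 8 and 7 in the interaction, and 12 and 21 between controls. With the yolk sac term they were 229 and 107 in G3, 120 and 27 in G17, and 576 and 367 in the common effect. At an adjusted p of 0.01 they were 161 and 74 in G3, 134 and 25 in G17, and 563 and 374 in the common effect; at 0.1 they were 670 and 550 in G3 and 517 and 411 in G17. In G17, 1 fit of all 16 embryos gave 546 and 498, the table the authors deposited had 334 lower, and the fit without the doubted libraries 90 lower. With sex as a term 1 gene, Gapdh (chosen after its value was seen), differed between controls, against 0. The yolk sac term uses the score that falls with genotype, so fewer calls follow in part from its construction.

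Lists past the test numbered 0 in G3, 0 in G17 and 1 in the common effect with an estimated correlation, 5, 0 and 4 with directional fry, and 17 in G17 and 27 in the common effect with mixed fry; without the doubted libraries G17 had 5. Genes shared by the lines numbered 287 higher and 118 lower at 0.1, and 77 and 11 with the yolk sac term. Of genes called in either line, 92.2% had the same sign at 0.1, 97.7041% with the yolk sac term and 97.6663% without the doubted libraries. Pearson's r was 0.646 at 5 or more CPM, 0.358 with edgeR and TMM, 0.197 with the yolk sac term and 0.282 without the doubted libraries.

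Leaving out each embryo in turn gave 213 (without G3 mutant 29) to 556 (without G3 control 18) genes higher and 126 to 329 lower in G3, and 169 (without G17 mutant 42) to 378 higher and 50 (without G17 mutant 42) to 296 lower in G17. The common effect ranged from 845 to 1075 higher and from 708 to 913 lower, the interaction stayed at 1 and 1, and the controls at 0. Greb1l ranged from 0.79 to 0.98 in G3, from -1.38 to -1.13 in G17, from -0.31 to -0.06 in the common effect and from 1.998 to 2.24 in the interaction. Lists ranged from 8 to 16 in G3, 6 to 9 in G17 and 6 to 12 in the common effect. Shared genes ranged from 118 (without G17 mutant 42) to 212 higher and from 19 (without G17 control 35) to 62 lower, same signs from 93.6% to 97.3% and r from 0.260 to 0.302. With 4 embryos per group, 2-fold changes were recovered for 53.7% of simulated genes in G3 and 40.3% in G17 at the measured depths; neither depth nor the number of embryos was varied.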

Other observations

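All 5 tests of gene families in this part, and the tests of scores per embryo, were chosen after the results were seen, and 9 families were looked at. Single genes of fuel use were called in the common effect, and the genes named in this part were chosen after their values were seen. Oxct1 rose by 1.94 ± 0.20 (log2, SE, limma adjusted p = 1.75e-06), Eci1, an enzyme gene of unsaturated fatty acid oxidation, by 1.80 ± 0.16, the electron transfer flavoprotein gene Etfa by 0.93 ± 0.09, the fatty acid carrier gene Fabp3 by 1.64 ± 0.20, and Hadha, of the trifunctional protein, by 0.29 ± 0.05. Hadha passed in neither line alone (limma adjusted p = 0.0766 in G3 and 0.0519 in G17). In the same family Cd36 (-1.06 ± 0.26) and Acsl1 (-0.34 ± 0.11) fell in the common effect. Cd36 passed in G17 (limma adjusted p = 0.0337) but not in G3 (0.319), and Acsl1 in neither line (0.301 in G3 and 0.212 in G17). Single genes of sterol synthesis were called as well: Hmgcs1 rose by 0.77 ± 0.10, Insig1 by 0.81 ± 0.14, Cyp51 by 0.64 ± 0.09 and Acat2 by 0.54 ± 0.07. Among imprinted genes, Plagl1 rose by 0.94 ± 0.09 and Peg3 by 0.32 ± 0.08, while Mest fell by 0.46 (SE 0.05) and Phlda2 by 1.55 (SE 0.19). Peg3 passed in G3 (limma adjusted p = 0.000135) but not in G17 (0.556). Of head neuroectoderm genes, Otx2 rose by 0.92 ± 0.26, its call ending in 5 of the 16 fits that left out an embryo. Otx2 passed in neither line alone (limma adjusted p = 0.22 in G3 and 0.152 in G17).

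Near Greb1l on chromosome 18, Gata6 rose by 0.36 ± 0.08, the transcript 1010001N08Rik (10987944 to 11052567, minus strand), which overlaps the start of Gata6, rose by 0.64 ± 0.15, Abhd3 rose by 2.79 ± 0.84, and Snrpd1 (-0.20 ± 0.05), Usp14 (-0.16 ± 0.05) and Rmc1 (-0.38 ± 0.12) fell in the common effect. The calls of Abhd3, Usp14 and Rmc1 ended in 10, 12 and 13 of the 16 fits without an embryo. None of these neighbours passed in G17 alone. In G3 alone, Gata6, 1010001N08Rik and Snrpd1 passed (limma adjusted p = 0.0309, 0.0278 and 0.0126), and Abhd3, Usp14 and Rmc1 did not. Reads of Gata6 and 1010001N08Rik cannot be separated if strand was not kept, which the sources used here do not give.

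Whether such genes stand for wider families was tested for 4 families without the genes that had drawn attention to them, and for the neighbours of Greb1l on all genes in a window set by distance. None of the 5 tests passed after Benjamini-Hochberg adjustment, and the lists were written after values of many members had been seen. Without the rising fuel genes above and Acadl, genes of fatty acid and ketone body oxidation had a median of 0.10, with 4 of 20 higher and 2 lower, Cd36 and Acsl1 (camera with an estimated correlation, p = 0.179, adjusted p = 0.298). Without the sterol genes seen beforehand, the family was positive at 18 of 18 with a median of 0.28 and 6 called (camera with an estimated correlation, p = 0.0511, adjusted p = 0.128), so a joint rise of the pathway is not established. Other midbrain-hindbrain and placode genes had a median of -0.27, with 2 of 14 called higher, Otx2 and Lmx1b, and 0 lower (camera with an estimated correlation, p = 0.739). Pax2, Pax5, Pax8, Wnt1, Fgf3, Ret, Ngfr, Sox10, Foxd3 and Foxi2 were among the genes that had drawn attention to them. Imprinted genes other than those above, H19 and Igf2 changed at 13.6% (3 of 22) against 9.39% of other genes (Fisher's exact p = 0.342, adjusted p = 0.428). Genes within 2 Mb of Greb1l changed at 23.1% (6 of 26, the 6 named above) against 9.38% (Fisher's exact p = 0.0304, adjusted p = 0.128).

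Scores per embryo were compared within lines by an exact stratified permutation test of 4900 arrangements, for 33 lists with the sex-linked list. The p of 0.000408 is the smallest that the arrangements allow, and 4 lists reached it (adjusted p = 0.00337). These were ribosome biogenesis (-0.27 in G3 and -0.22 in G17), p53 targets (0.64 and 0.43), neural crest (-0.78 and -1.26) and early embryo genes (1.18 and 1.53). A few genes can carry such mean scores: the neural crest list medians were -0.14 and -0.13, the G17 median without Foxd3, which was not tested there. With an estimated correlation the camera adjusted p in the common effect was 0.308 for p53 targets and 0.553 for neural crest and for early embryo genes. Proepicardium scores were higher (0.68 and 0.32, exact p = 0.00694, adjusted p = 0.0458), although 5 of 10 members were positive in the common effect with a median of 0.08 (camera adjusted p = 0.317), and yolk sac scores lower (-0.97 and -2.15, exact p = 0.00898, adjusted p = 0.0494; camera adjusted p = 0.553 with an estimated correlation). The sarcomere score (0.17 and 0.50) did not pass (exact p = 0.0437, adjusted p = 0.18), nor did the mitotic score (exact p = 0.0392, adjusted p = 0.18).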
